A study of Penicillium oxalicum with 6 samples.

How the data were processed

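RNA sequencing of mycelium of Penicillium oxalicum, a filamentous fungus that secretes enzymes which break down plant biomass, gave 6 libraries. The sample labels place 3 libraries in medium with 1% Avicel, a microcrystalline cellulose, and 3 in medium with 1% wheat bran, each for 4 hours, all in the strain MuKu70. The title of the series instead names a deletion mutant of the gene POX07277 after transfer from glucose to Avicel for 24 hours. The names of the deposited tables also carry the number of this gene and 24 hours, differ between the groups by 1 letter, and name neither a medium nor 4 hours. The labels thus differ from the title in strain and time, and for the 3 libraries labelled wheat bran also in medium. They differ from the table names in time, and the sample labels name no POX07277 mutant. Libraries were grouped by their sample labels alone and are called the libraries labelled Avicel and the libraries labelled wheat bran throughout. Within each group the labels give the letters F, S and T. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

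Per the submitters' processing notes, the tools were BWA 0.7.10-r789, Bowtie2 2.1.0, RSEM 1.2.12 and DESeq2, with no role or order given. The genome build and annotation behind the gene models are not given in the sources used here, nor is whether the library kit kept strand. Reads of overlapping or antisense genes may therefore be mixed. Each deposited table holds an expected count (an estimated number of reads or fragments that need not be whole) and an FPKM value for 9834 genes, per the file headers. The expected counts are not normalized. They were exactly whole in 99.2% of values, and 109 genes had a value that was not whole in at least 1 library, as happens when reads are divided between similar genes. The FPKM values were scaled by the authors to gene length and to the reads assigned to genes: the length implied by count and FPKM differed between libraries by at most 0.701% for genes above an FPKM of 2. The deposited table of the library labelled wheat bran, replicate T, also holds TPM, which was not used.

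Expected counts totalled 14598919, 14455500 and 14310051 in replicates F, S and T labelled Avicel, and 13176152, 13428671 and 13645708 in those labelled wheat bran. A count of 0 was read as at most 3 counts, which is 0.222 to 0.225 CPM (counts scaled to a library of 1000000) in the libraries labelled wheat bran. Floors and counting intervals cover counting error only.

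The gene IDs run from POX00001 and carry no names in the files. None of the 9834 IDs matched any of the 9964 entries of the RefSeq table for assembly ASM172317v3, whose locus tags use another numbering: over 8489 pairs of entries with the same number, the correlation of log gene lengths was 0.0063. Names and positions were therefore not used, none of the 17 gene lists fixed by product name before the data were examined (among them cellulases, hemicellulases, sugar transporters, secondary metabolism and asexual development) was tested, and IDs are given for few genes.

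Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, quasi-likelihood F-test, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The design fixed before the data were examined named this test for count data and limma for FPKM. Fold changes are the libraries labelled Avicel over those labelled wheat bran. Filtering kept 8636 genes and removed 1198. CPM values are TMM-normalised, and the standard error (SE) of a log2 fold change was derived from its F statistic. Genes were named by a rule fixed before the data were examined: POX07277, and the 2 genes with the largest change in each direction among those past the threshold, with a mean FPKM of at least 10 in the higher group and no overlap between the groups. POX07277 met both parts of the rule, the second by a fitted value that depends on the prior count, since 1 group is at 0. Genes chosen after their values were seen are named as such.

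Clustering of changed genes along the ID numbers was tested by counting pairs of genes with consecutive numbers that were both called at 2-fold or more in one direction, against 10000 random reassignments of the calls to tested genes (one-sided permutation test). It describes the order of the IDs, since no genome position was paired with them. In simulated counts for this comparison (8636 genes, 200 changed), edgeR recovered 46.3% of 67 genes changed 1.5-fold, 89.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, with 12 false calls among 168. The simulation changed far fewer genes than the 4746 called in the data. The adjustment is stricter where few genes change, so these rates do not carry over to the data. Alternatives planned before the data were examined were other pseudocounts (limma 3.58.1 on log2 FPKM), other filters on low values, other scalings, limma with other moderation, an adjusted p under 0.01, a replicate block and leaving out each library. DESeq2 1.42.0, limma with a pseudocount of 1, robust edgeR, a filter on an FPKM of 1 and removal of each library's gene length trend were added after the data were seen, as were rankings of abundance by 1 group alone and by the lower of the group means. Whether letters pair the libraries was checked from the correlation of deviations from the group means. Figures were drawn with matplotlib 3.10.9.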

Results

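Expression of 9834 genes was measured in 6 mycelium libraries, 3 labelled Avicel and 3 labelled wheat bran, at 13176152 to 14598919 expected counts per library. The 10 most abundant genes took 9.1% to 11.5% of the counts of a library. Within a group, libraries correlated at a Pearson r of 0.9827 to 0.9953 over log2(CPM + 1) of tested genes, and between groups at 0.8819 to 0.9089. Principal component 1 held 87.7% of the variance and separated the groups. Replicate F labelled Avicel stood apart from replicates S and T on principal component 2, at 25 against -10.5 and -14.4, with 6.2% of the variance. No pair of libraries was a repeat of another within sampling noise: the median squared difference of counts was 3.63 times its sampling value in the closest pair.

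POX07277, the gene that the title of the series names as deleted, was read in every library labelled Avicel and in none labelled wheat bran. Its expected counts were 427, 375 and 331 in replicates F, S and T labelled Avicel, a level of 26.2 ± 3.29 CPM (SD, n = 3), or 10.7 ± 1.25 FPKM (SD, n = 3). It had 0 counts in all 3 libraries labelled wheat bran, which held 13176152 to 13645708 counts each. Against a floor of 3 counts per library, POX07277 was at least 117-fold higher in the libraries labelled Avicel (edgeR quasi-likelihood test, adjusted p = 8.69e-06). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allow. POX07277 was 1 of 5537 genes with at least 300 counts in each library labelled Avicel, and the only one of them at 0 in all libraries labelled wheat bran. The other 5536 kept at least 0.88% of their level. No gene with at least 300 counts in each library labelled wheat bran was at 0 in all of those labelled Avicel, where the lowest level kept was 0.27%. The cutoff of 300 counts was set after the data were seen, and these statements depend on it. POX09690, with 277 and 279 counts in replicates S and T labelled wheat bran, falls below it. That gene had 3 counts in all libraries labelled Avicel. The labels give the libraries 2 carbon sources in 1 strain and do not mention this gene, so every direction below is between the labelled groups, whose true difference is not settled by the labels.

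The genes with ID numbers next to POX07277, chosen after their values were seen, were read in both groups. The gene one number below was 1.39-fold lower in the libraries labelled Avicel (log2 fold change -0.48, SE 0.07, edgeR adjusted p = 0.000892). The gene one number above had a log2 fold change of -0.29 (SE 0.10, edgeR adjusted p = 0.0469). Its call was lost in 14 of 21 alternatives, and the adjusted p ranged from 0.0251 to 0.16 over all 21.

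**Figure D1:**
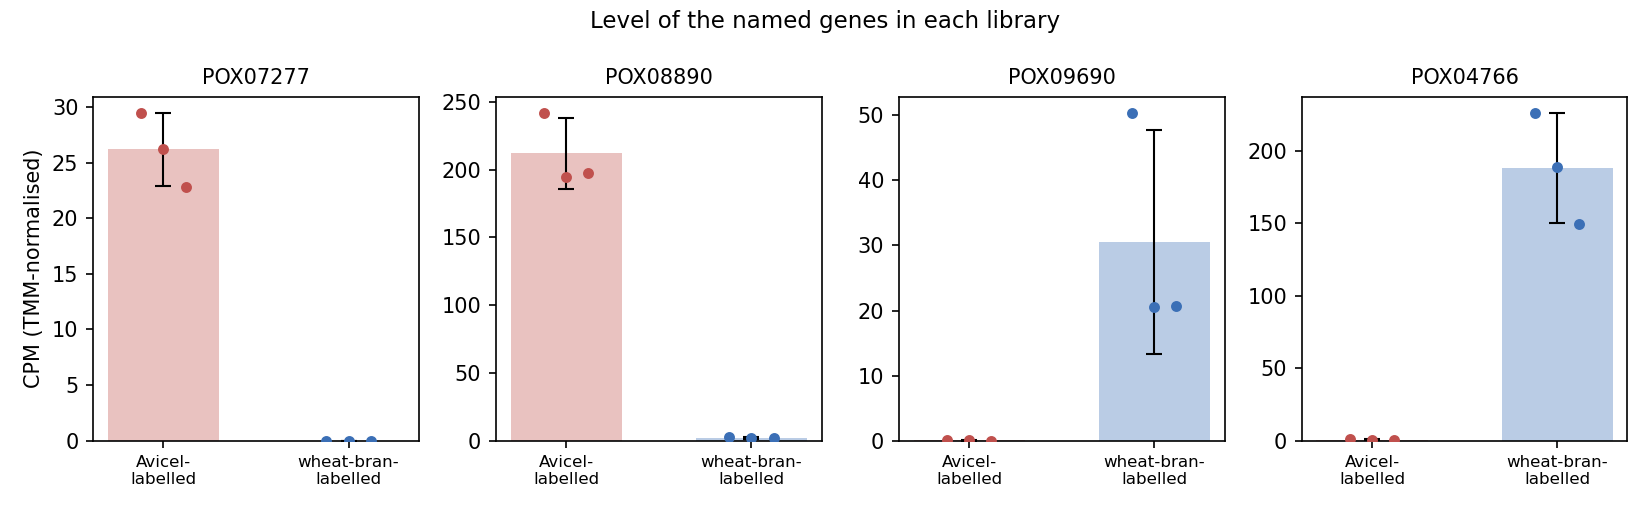
Level of the 4 named genes in each library, in TMM-normalised CPM on linear axes that start at 0. Points are libraries, bars are means of 3 libraries and error bars are SDs. POX07277 is at 0 in all 3 libraries labelled wheat bran. The groups of each gene do not overlap, which the rule required of genes named for the size of their change.

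The comparison of the groups asked which genes differ in expression between the libraries labelled Avicel and those labelled wheat bran. Of 8636 tested genes, 4746 (55%) passed the threshold, 2373 higher and 2373 lower in the libraries labelled Avicel (edgeR quasi-likelihood test, adjusted p under 0.05). The even split depended on the setting: 2578 were higher and 1923 lower once each library's gene length trend was removed, and with limma on log2 FPKM 2642 were higher and 2035 lower under quantile normalization, against 2266 and 2350 without it. Most of these changes were small: 3326 genes (70.1%) changed less than 2-fold. At 2-fold or more, 607 genes were higher and 813 lower, against 721 higher and 679 lower with the length trend removed, so this excess of lower genes turned with the setting. That setting covered 8442 genes and also re-centred the fold changes, with a median log2 fold change of 0.067 against 0.0086. At 4-fold or more, 159 were higher and 360 lower (171 and 318 with the length trend removed), and at 16-fold or more 15 were higher and 128 lower (18 and 119). Counts of large changes depended on the pseudocount and the scaling. At 16-fold or more, limma on log2 FPKM gave 17 higher and 123 lower with a pseudocount of 0.1. It gave 6 and 84 with a pseudocount of 1, and 10 and 76 under quantile normalization. A pseudocount of 5 gave 5 and 52, and left 85 and 197 at 4-fold or more. The groups did not overlap for 5558 genes (64.4%), where chance gives 10%. With each library left out in turn, 3911 to 4997 genes passed, 1375 to 1477 of them at 2-fold or more. Among these fits with a library left out, the number that passed rose above 4746 only without replicate F labelled Avicel.

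The 607 genes that were at least 2-fold higher took 23.62% ± 1.55 of all counts in the libraries labelled Avicel and 7.11% ± 0.40 in those labelled wheat bran (SD, n = 3 each). The 813 genes that were at least 2-fold lower took 4.83% ± 0.51 and 20.31% ± 0.85 (SD, n = 3 each). These sets were chosen on the same libraries, so the shares describe their size and are not independent evidence. The other 7216 tested genes took 71.52% ± 1.05 and 72.56% ± 0.57 (SD, n = 3 each).

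Changes of 2-fold or more were also counted by abundance. Of the 100 genes with the highest mean FPKM over all libraries, 42% were called at 2-fold or more, 20 higher and 22 lower, against 16.1% of the other 8536. A large change itself lifts a gene in this ranking, so it was repeated in other ways, chosen after the data were seen. Ranked by the lower of the group means, which a large change pulls down, 24% of the top 100 were called, 13 higher and 11 lower, against 16.4% of the rest. Ranked by the libraries labelled Avicel alone, 43% were called, 35 higher and 8 lower, and by those labelled wheat bran alone 40%, 6 higher and 34 lower. Fisher's exact test was made for the ranking over all libraries alone (odds ratio 3.76, 95% interval 2.46 to 5.72, two-sided p = 1.02e-09) and carries the bias of that ranking; the other rankings were not tested. In the ranking over all libraries, of the next 400 genes, 22% were called, 40 higher and 48 lower. The share was 17.4% among the 1500 genes at ranks 501 to 2000, and 15.5% among the remaining 6636, with 425 higher and 604 lower. The gene with the most counts in the libraries labelled wheat bran stood at 28900 ± 983 CPM there and at 1590 ± 432 CPM in those labelled Avicel (SD, n = 3 each), an 18.1-fold difference (edgeR adjusted p = 9.7e-06). Its expected counts were not whole, and its level is uncertain where reads are shared with a similar gene. The gene with the most counts in the libraries labelled Avicel was 3.28-fold higher there, at 19900 ± 1380 against 6070 ± 1220 CPM (SD, n = 3 each; edgeR adjusted p = 0.000268). Both genes were chosen after their values were seen.

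**Figure D2:**
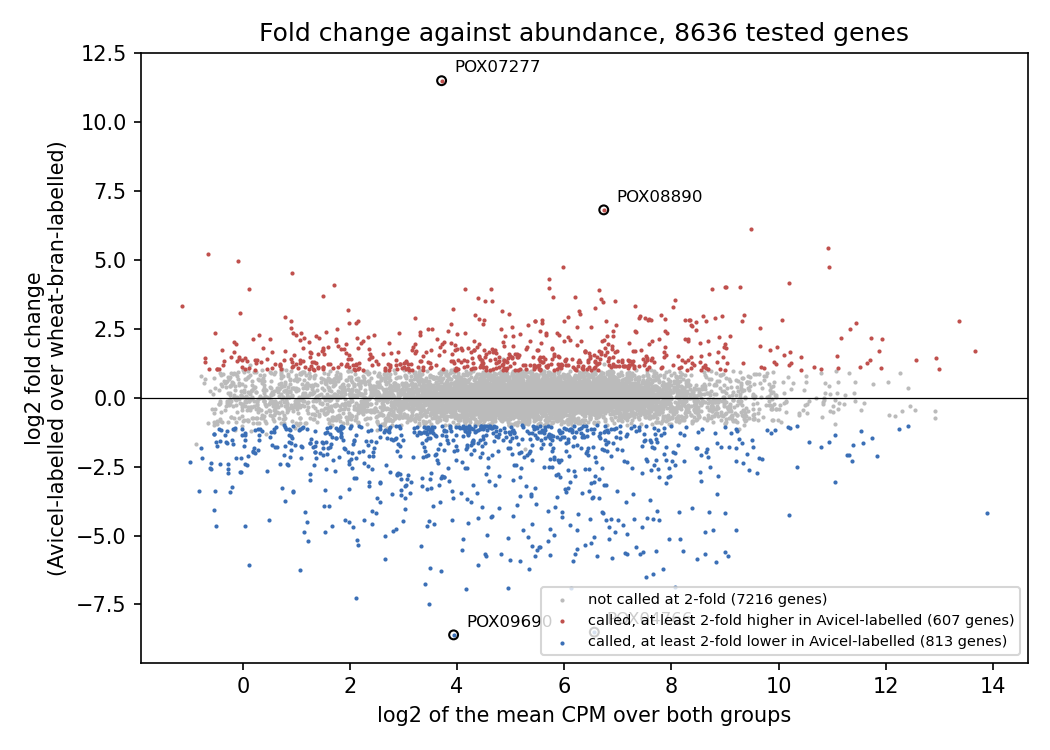
Log2 fold change (libraries labelled Avicel over those labelled wheat bran) against the log2 of the mean CPM of both groups, 1 point per tested gene. Red points are the 607 genes called at least 2-fold higher and blue points the 813 called at least 2-fold lower; apart from POX07277 the blue points reach further from 0, and the fitted value of POX07277 depends on the prior count because 1 group is at 0.

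The other gene that the rule named for an increase was POX08890. It stood at 212 ± 26.3 CPM in the libraries labelled Avicel and 1.86 ± 0.465 CPM in those labelled wheat bran (SD, n = 3 each), a 113-fold difference (log2 fold change 6.82, SE 0.18, edgeR adjusted p = 5.79e-07). The largest decreases were those of POX09690 and POX04766. POX09690 had 3 counts in all libraries labelled Avicel and 1228 in those labelled wheat bran, a ratio of summed levels of 439 with a 95% counting interval of 150 to 2130 (edgeR adjusted p = 5.65e-05). Its level in the libraries labelled wheat bran was 30.5 ± 17.2 CPM (SD, n = 3), and its log2 fold change of -8.61 became -8.04 without replicate F labelled wheat bran and -9.45 without replicate S labelled Avicel. POX04766 fell from 188 ± 38 CPM in the libraries labelled wheat bran to 0.508 ± 0.353 CPM in those labelled Avicel (SD, n = 3 each), a 364-fold difference (log2 fold change -8.51, SE 0.32, edgeR adjusted p = 1.28e-06). Without replicate F labelled Avicel its log2 fold change was -9.19. The files give no names for these IDs.

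Changed genes lay close together along the ID numbers. Among genes called at 2-fold or more, 332 pairs with consecutive numbers changed in the same direction, against 107.4 expected when calls were reassigned at random and 147 in the highest of 10000 reassignments (one-sided permutation p = 1e-04, the smallest they can give). Across genes, which are not independent replicates, log2 fold changes of genes 1 number apart correlated at r = 0.334, those 3 apart at 0.126 and those 10 apart at 0.035. The highest of 1000 shuffles reached 0.033 at a distance of 1 and 0.038 at a distance of 10.

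**Figure D3:**
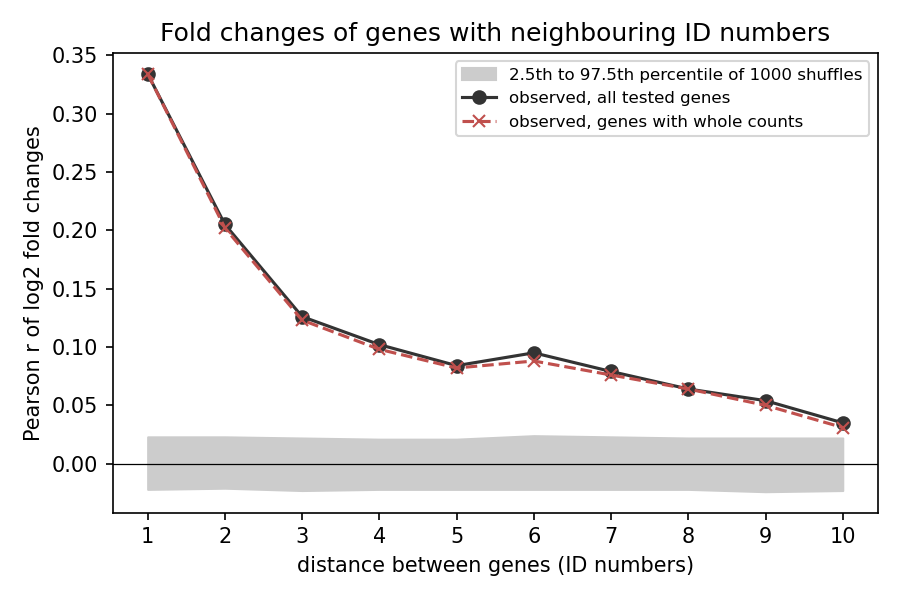
Pearson correlation of log2 fold changes between genes whose ID numbers lie 1 to 10 apart, for all tested genes (circles) and for genes with whole expected counts (crosses). The grey band spans the middle 95% of 1000 shuffles; the correlation falls from 0.334 at a distance of 1 to 0.035 at a distance of 10.

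Runs of at least 5 consecutive ID numbers, all called at 2-fold or more in one direction, numbered 13 and held 97 genes, 7 runs lower and 6 higher in the libraries labelled Avicel. The mean over 1000 random reassignments was 0.048 runs and the highest was 1. The longest run held the 22 genes numbered 5850 to 5871, chosen after their values were seen. All 22 were lower in the libraries labelled Avicel, with a median log2 fold change of -4.91 and sizes from 1.67 to 6.39. Their summed level was 241 ± 85.1 CPM in the libraries labelled Avicel and 4830 ± 724 CPM in those labelled wheat bran (SD, n = 3 each), a 20.0-fold difference. POX09690 lay in a run of 8 genes, numbered 9684 to 9691, with a summed level of 95.8 ± 7.14 against 963 ± 225 CPM (SD, n = 3 each). The longest of the 6 higher runs held 9 genes, with a summed level of 3950 ± 1440 against 969 ± 271 CPM (SD, n = 3 each).

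**Figure D4:**
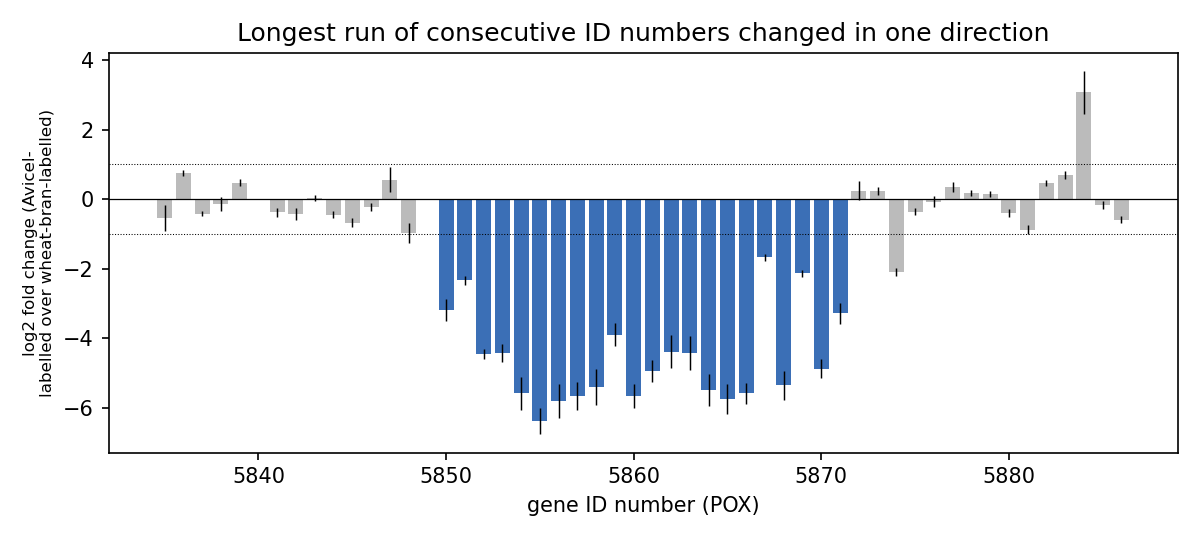
Log2 fold change (libraries labelled Avicel over those labelled wheat bran) of tested genes along the ID numbers around the run of 22 genes (blue), with error bars of 1 SE and dotted lines at a 2-fold change. Every gene of the run is lower by 1.67 or more on the log2 scale.

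Fold changes also went with gene length, taken from the ratio of counts to FPKM for 8442 of the tested genes. This implied length is an effective one and need not equal the length of the transcript. Across genes, the Spearman correlation of log2 fold change with length was 0.20. The median log2 fold change was -0.18 in the shortest of 5 equal classes of genes, with a median length of 405 bases, and 0.18 in the longest, with a median of 2780 bases. With each library's length trend removed, 1400 of these 8442 genes were called at 2-fold or more and 51.5% of them were higher in the libraries labelled Avicel. Without the correction it was 42.7% of the 1420 calls, which were made over all 8636 tested genes and so on a somewhat larger set.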

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

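The count of genes past the threshold stayed within 1.5 times 4746 in all 22 alternatives (3251 at an adjusted p under 0.01, 3911 to 4997 with each library left out, the highest without replicate F labelled Avicel). The count at 2-fold or more stayed within 1.5 times 1420 in 21 of 22. It was 892 with a pseudocount of 5 on log2 FPKM, which by construction shrinks the folds of weakly expressed genes. With the letter as a replicate block, 4602 genes were called and 1420 at 2-fold or more. Deviations of same-letter libraries correlated at 0.17, -0.08 and 0.19 for F, S and T, against -0.26 to 0.16 for different letters. The F and T pairs lay above every different-letter pair and the S pair did not. Whether the letters pair the libraries stays open, and the main test takes them as unpaired. Not every library correlated best with its own letter. POX07277, POX08890, POX09690 and POX04766 kept direction and call in all 21 alternatives each. Clustering along the ID numbers kept its direction and call in all 22. The gap between the lowest r within a group and the highest r between groups was 0.0738. It was 0.0855 on log2 FPKM with a pseudocount of 0.1, 0.0465 with no filter, 0.1005 with a filter on an FPKM of 5, 0.0678 with a filter on an FPKM of 1, and 0.0738 to 0.085 with each library left out. The cause was not tested. Gene list tests were not run, because no names were paired with the IDs. A floor of 3 counts per library limits POX07277 in the libraries labelled wheat bran to under 0.852% of its level in those labelled Avicel, and the 95% counting interval of the summed counts to 0.35%. Of the 100 most abundant genes, 42 were called at 2-fold or more, and 24 when ranked by the lower of the group means. An adjusted p under 0.01 left 1577 genes higher and 1674 lower, and a pseudocount of 5 left 352 higher and 540 lower at 2-fold or more.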

Other observations

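The tests in this part were chosen only after the data were seen, and the bound of the gene length test was set before its own result was seen.

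Other runs of consecutive ID numbers also changed by large factors. Between the libraries labelled Avicel and those labelled wheat bran, a run of 9 genes numbered 9467 to 9475 had summed levels of 111 ± 48.6 and 2530 ± 301 CPM (SD, n = 3 each). A run of 6 genes numbered 3409 to 3414 had 40.7 ± 8.54 and 928 ± 34.9 CPM, and a run of 5 genes numbered 7388 to 7392 had 8.42 ± 1.8 and 187 ± 17.8 CPM. In the other direction, 5 genes numbered 3927 to 3931 had 2620 ± 443 and 167 ± 55.2 CPM, and 6 genes numbered 9352 to 9357 had 1870 ± 211 and 180 ± 4.17 CPM.

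POX07277 was at 0 in all 3 libraries labelled wheat bran. Too few reads cannot account for this, since the lowest level labelled Avicel was 102 times the highest floor of 3 counts. A swap of 1 or 2 libraries between the groups is argued against, since every library labelled Avicel had at least 331 counts and every other had 0, and 0 of 6 libraries lay on the other group's side of principal component 1. An exchange of the labels of all libraries would leave the same 0 and stays open. A candidate explanation is that the gene is missing from the strain behind the libraries labelled wheat bran, as a deletion mutant would show. The sample labels would then not describe these libraries. POX07277 was the 1 gene among those with 300 counts or more in each library of a group that was at 0 in all of the other group. That count depends on the cutoff of 300, which was set after the data were seen and lies below the gene's own lowest count of 331. It therefore adds little to the 0 counts themselves. An intact gene that is silent in those libraries stays open, because RNA reads do not show whether a gene is present. The least retained of the other 5536 genes kept 0.88%, while the 95% counting interval of the summed counts leaves POX07277 at most 0.35%. In the other direction a gene read in both groups kept 0.27%, so a level under 0.35% was also met without a count of 0 in the whole group. The names of the deposited tables carry the 24 hours of the title and not the labelled 4 hours. Labels, title and table names each give the same time for every library, and the expression values do not settle medium or time. The 4746 called genes may thus reflect strain, medium or both, and no source names a difference in time between the groups. A difference in culture or library preparation between the groups cannot be told apart from these. Nothing in the labels says that libraries of a group came from separate cultures.

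Genes with neighbouring ID numbers changed together. Reads divided between near-identical genes are argued against as the whole cause. Only 83 of the 8636 tested genes had expected counts that were not whole, and the correlation at a distance of 1 was 0.334 without them. So few genes could hardly move it. Reads given whole to 1 of several similar genes would not be seen in this way, and the role of each tool is not given. Read-through or overlap between adjacent genes is argued against as the whole cause, because genes 3 numbers apart still correlated at 0.126, above the highest shuffle of 0.036; it may add to the correlation of immediate neighbours. Groups of co-regulated genes that lie together on the genome, such as clusters for a secondary metabolite, are a candidate explanation for the 13 runs. This stays open because no genome position or product name was paired with the IDs.

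Longer genes tended to be higher in the libraries labelled Avicel. Relative to the mean of all 6 libraries, the slopes were 0.065, 0.072 and 0.057 log2 units per doubling of length in replicates F, S and T labelled Avicel, and -0.09, -0.053 and -0.052 in those labelled wheat bran; the opposite signs of the group averages follow from this centring. A length trend of this size is argued against as the whole cause of the 2-fold changes. Median log2 fold changes ran only from -0.18 in the shortest class to 0.18 in the longest. After each library's trend was removed, 87% of the 1420 calls remained, with genes that had no length counted as lost. Removal of so small a trend could hardly undo calls far from the 2-fold bound, so this share adds little. Whether the trend itself comes from the libraries or from the genes that changed was not tested. Length bias may still set part of the split between higher and lower genes, which was 51.5% higher after the correction. The correction also moved the median log2 fold change from 0.0086 to 0.067. With limma on log2 FPKM, quantile normalization alone gave a median of 0.068, against -0.0014 without it. Effects of length and of re-centring on the split are therefore not told apart.

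The real split of the 6 libraries gave 4746 called genes, 1420 of them at 2-fold or more; of all 10 splits into 3 and 3 it was the 1 split with as many, for either count. The other 9 splits gave 0 genes by edgeR for either count, 16 to 258 genes at an unadjusted p under 0.05, and at most 4 genes by DESeq2. Each of these other splits puts libraries of both labelled groups on each side, so the difference between the groups widens the spread within a side. Few calls were then likely beforehand, and these splits do not show how many calls chance alone would give. With 10 splits the share also cannot go under 0.1, which is too few for a share under 0.05.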
